A study of Homo sapiens with 2 samples.

How the data were processed

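RNA bound to FLAG-tagged human Ago2 was measured in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, cells were transfected with plasmids, lysates were incubated with FLAG beads, and RNA was isolated from the washed beads. There were 2 samples in 2 groups, wildtype Ago2 and mutant Ago2, with 1 array per group. The labels do not say which residue was mutated, and no array of a mock immunoprecipitation or of input RNA was analysed here.

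Each array had 2 colours. Per the labels' protocols, RNA was ligated to a linker carrying DY547, and the other channel held DNA oligonucleotides for a subset of mammalian miRNAs labelled with Alexa Fluor 647. The reference was therefore synthetic and was no sample of either group. Per the file headers, spots were quantified with BlueFuse for Microarrays version 3.6. The 4704 spots of each array were combined by the authors into 1147 named rows as the mean over spots of a name, on average 4.1 spots per row, with empty fields for normalization and exclusion. The number of spots behind each row, the individual spots and a background column were not in the files used here, and the treatment of the background is not given in the sources used here.

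Per the file headers, the intensity columns held the linear amplitude of each channel. The deposited log2 columns held the mean log2 ratio of sample over reference and its SD between replicate spots. The deposited fraction columns held, per channel, the estimated probability from 0 to 1 that a spot is on. The series matrix held 1141 of the rows, and its linear intensity values, as deposited by the authors, were identical to the sample-channel amplitudes of the same arrays, with a largest difference of 0. Its column medians were 159.5 with wildtype and 116.7 with mutant Ago2. It is not centred, and it holds the sample channel alone, so no direction is in question.

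Probes were sorted by name into 467 human miRNA probes, 246 mouse or rat probes, 119 probes of other animals whose miRNA name also stands on a mammalian probe, and 201 worm, fly or fish probes whose name does not. The last set served as the negative probes. Probe sequences were not in the files used here, so negative probes close in sequence to a mammalian miRNA could not be removed. Counts of negative probes on may therefore include signal of such miRNAs. A probe was called on when its sample-channel probability was above 0.5. The rule fixed before the data were examined took the file's detection flag for the sample channel where there is one, and otherwise an amplitude above the median plus 3 MAD-based SD of negative probes. The files hold no flag for the sample channel alone. Their confidence flag covers both channels and was not used for detection, and each channel has a probability. Reading the sample-channel probability as the flag, and the limit of 0.5, were chosen after the data were seen. The amplitude rule was run beside it. Its limits were 452.4 with wildtype and 478.2 with mutant Ago2.

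The main value was the deposited log2 ratio of sample over reference, with each array centred on its median over the human probes on on both arrays. The planned background correction was not run, since no background column was there, so amplitudes were used as given. For a probe on on 1 array only, a lower bound of the fold was computed against the higher of its own mutant-array amplitude and 487.2, the lowest amplitude among probes on on the mutant array. The bound was given for the sample channel as scanned and for the centred ratio, and a ratio bound is printed for a named miRNA only where its reference channel was on on both arrays. With 1 array per group no test between groups was possible, and no p-value is given. The SD between replicate spots covers spot error within an array only, and a standard error could not be formed without the number of spots. The number of arrays limits the precision.

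The named miRNAs follow a rule fixed before the data were examined. It takes up to 12 per direction past 2-fold among probes on on both arrays, up to 5 per direction with the largest lower bound (ranked on the centred ratio) among probes on on 1 array, up to 4 members per fixed list in the order written, and miR-451. Its requirement that replicate spots not overlap could not be applied without individual spots. The 27 fixed lists hold miRNA families, genomic clusters, tissue-restricted miRNAs as markers of other cell types, and miR-451. Other miRNAs named were chosen after their values were seen.

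List medians were set against 10000 random lists of the same size, matched on mean log2 sample amplitude in 5 bins. On simulated data for 467 probes with lists of 8, 20 of 20 runs with a log2 shift of -3 and 17 of 20 with a shift of -1 fell below the 5th percentile, against 1 of 20 without a shift. With a shift of 1, 13 of 20 lay above the 95th percentile, against 2 of 20 without a shift. The simulated values were independent, unrelated to amplitude and less spread than the real unfiltered differences (SD 2.45). Most fixed lists were also smaller, so these rates do not carry over to the percentiles given here. In simulated bounds, 0 of 102 exceeded the true fold. The simulation only added signal to the dim array and put no noise on the bright one. That outcome was thus fixed in advance and checks the arithmetic alone. The alternatives were loess within each array, other centring, the sample channel alone, quantile normalization, other detection rules, mammalian probes and the series matrix. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1, the last for loess (span 0.3, 4 iterations) and quantile normalization.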

Results

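The miRNAs bound to wildtype and to mutant human Ago2 were compared in 293T cells. Ago2 is the Argonaute protein that holds a miRNA and can cleave a matching RNA. Each FLAG immunoprecipitate was hybridised to 1 array, so the array and the group cannot be told apart and no difference has a replicate check. The ratio of signal to background in the sample channel was 4.67 with wildtype and 2.49 with mutant Ago2, and in the reference channel 3.63 and 4.68. The median SD of the log2 ratio between replicate spots was 1.18 and 1.16. Per the file headers, 87.6% of spots with wildtype and 90.2% with mutant Ago2 fell in confidence class E, the last class. Class B held 0.02% on each array.

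Human miRNAs gave signal with wildtype Ago2 and almost none with mutant Ago2. Of 467 human miRNA probes, 48 were on with wildtype and 3 with mutant Ago2. The 3 were also on with wildtype, so 45 miRNAs were on with wildtype only and 0 with mutant only. Over these 45 the median sample amplitude was 647.4 with wildtype and 117.2 with mutant Ago2. Among the 201 worm, fly and fish probes the medians were 154.3 and 152.4, and 5 and 1 probes were on. On the mutant array, 44 of the 45 lay at or below 393.3, the 95th percentile of those negative probes. Lower values with mutant Ago2 follow in part from how the 45 were chosen, so their number is the finding, and their size is given only as a bound.

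**Figure D1:**
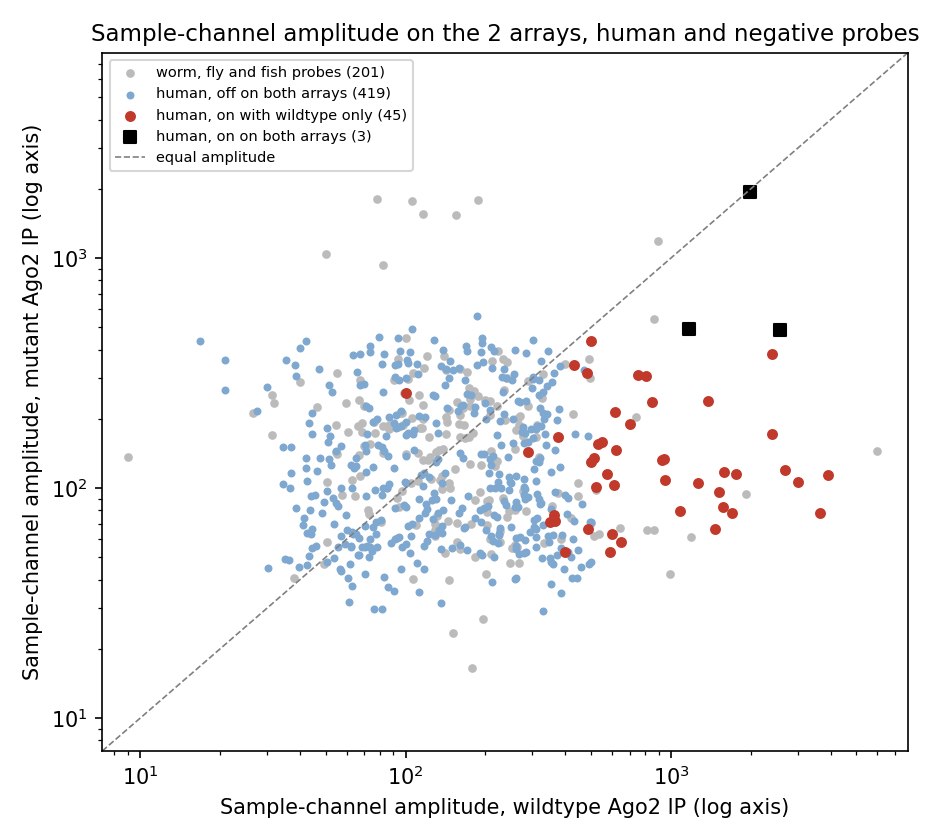
Sample-channel amplitude of each human (blue, red, black) and each worm, fly or fish (grey) probe with wildtype Ago2 (x) and mutant Ago2 (y), both in scanner units on log axes, with 1 point per probe and a dashed line at equal amplitude. Most of the 45 human probes on with wildtype only (red) lie far below the line, and the 3 on on both arrays (black squares) include miR-646 close to it.

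Ranked on the centred ratio, the largest lower bounds belonged to miR-103, miR-107, miR-20a, miR-625 and miR-20b. Of these 5, the reference channel was on on both arrays for miR-107 alone; for miR-20b it was 93.6 with wildtype and 440.9 with mutant Ago2, and for miR-625 155.0 and 640.0, so the order rests in part on the reference. In the sample channel the order was another, led by miR-106a with at least 8.01-fold, miR-103 and miR-17-5p with at least 6.16-fold. The sample amplitude of miR-103 was 3645 with wildtype and 77.8 with mutant Ago2, at least 7.48-fold lower in the sample channel. For miR-107 the amplitudes were 2695 and 120.0, a bound of at least 5.53-fold in the sample channel. Its bound as a centred ratio was 7.08-fold. That value rests in part on its reference, 729.9 with wildtype and 1880 with mutant Ago2, and on the centring. The amplitude of miR-20a was 2410 against 382.6, which gave at least 4.95-fold. For miR-625 it was 1472 against 66.1, at least 3.02-fold, and for miR-20b 1265 against 105.2, at least 2.60-fold, all in the sample channel. In the sample channel as scanned, the bound was above 1 for 35 of the 45, so it shows no fall for the others. The bound reached 2-fold for 15 of the 45 there. As a centred ratio it did so for 24, of which 9 had the reference channel on on both arrays, as 17 of the 45 did. It reached 2-fold for 37 as a ratio without centring and for 0 in the sample channel centred on the 3 probes on on both arrays, so the count depends on the scaling.

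The growth-associated cluster that runs from miR-17 to miR-92 had all 6 members of its fixed list on with wildtype Ago2 and 0 on with mutant Ago2. Outside the list, miR-17-3p was on with wildtype only and miR-18a* was off. Among the 6 were miR-17-5p (2999 with wildtype, 106.4 with mutant), miR-18a (1578 and 82.6), miR-19a (2398 and 171.5) and miR-20a. The same held for all 6 of the miR-17 seed family, which shares members with the cluster, and for all 3 of its paralogous cluster, miR-106b (588.0 and 52.6), miR-93 (1384 and 240.3) and miR-25 (924.0 and 132.5). Both members of the miR-103 and miR-107 family and both of the miR-221 and miR-222 cluster were on with wildtype only. The amplitude of miR-221 was 647.4 and 58.5, and that of miR-222 was 618.3 and 146.9.

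Other broadly expressed families were on in part with wildtype, and 0 of their members were on with mutant Ago2. Of the let-7 family, which restrains growth genes, 4 of 9 human probes were on. The human let-7a probe was off, with a probability of 0.44 with wildtype, while a probe for let-7a of mouse and fly was on with wildtype only, at 799.5 and 65.1. The amplitude of let-7b was 521.1 and 100.9, while let-7c had 431.0 and 344.0 and nearly equal log2 ratios. The miR-15 and miR-16 family had 3 of 6 on, with miR-16 at 1704 and 77.6 and miR-195 at 1522 and 96.2. The miR-30 family had 3 of 5 on, with miR-30b at 938.1 and 134.4. The family of miR-10, miR-99 and miR-100 had 3 of 5 on, with miR-10a at 951.1 and 108.9. The family of miR-25 and miR-92 had 2 of 6 on, the clusters of miR-23, miR-24 and miR-27 2 of 5, and the miR-29 family 1 of 3. Probes of near-identical family members can bind each other's miRNAs, so members are not independent.

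**Figure D2:**
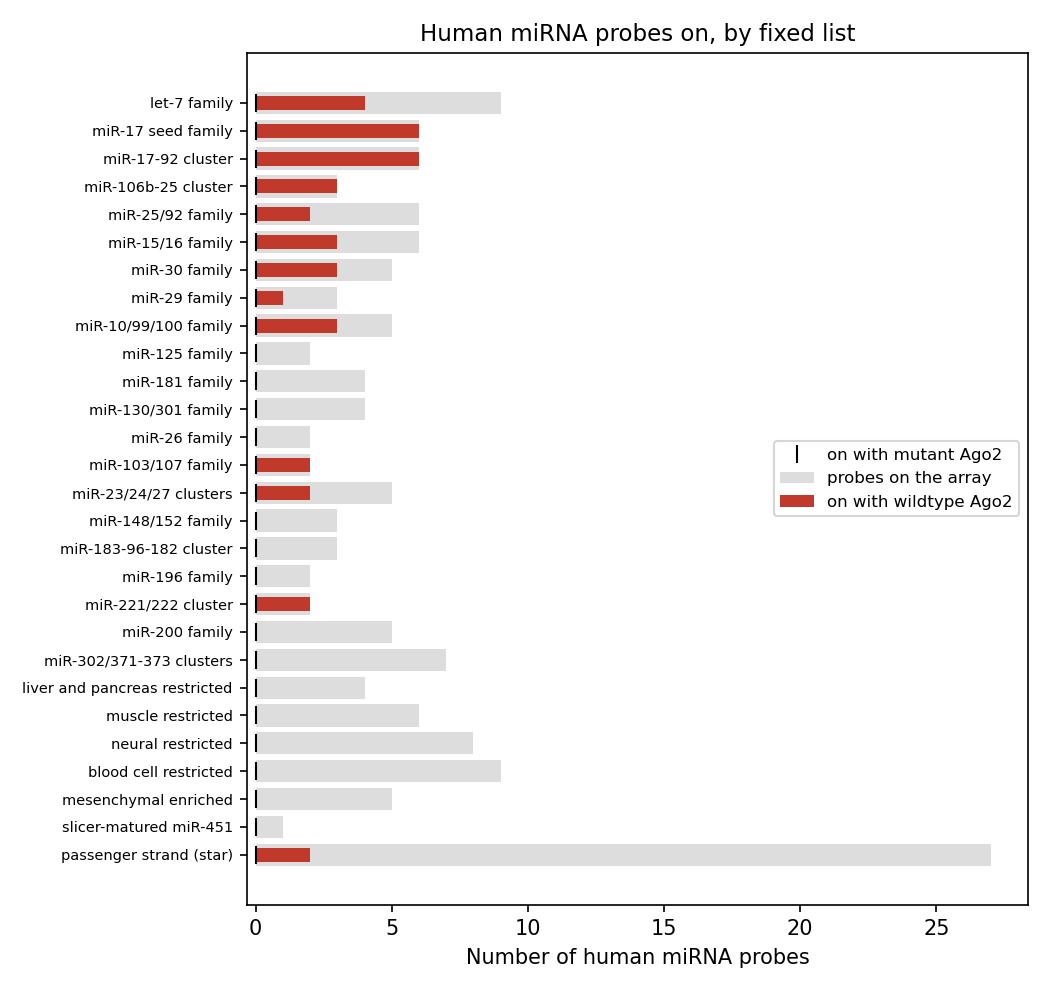
Number of human miRNA probes on the array (grey bars), on with wildtype Ago2 (red bars) and on with mutant Ago2 (black ticks) in each fixed list, with the lists on the vertical axis. All 6 listed probes of the cluster from miR-17 to miR-92 were on with wildtype, and each list has its tick for mutant Ago2 at 0.

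The markers of other cell types in the 5 fixed lists were off on both arrays. miRNAs outside these lists were not sorted by cell type. In the liver and pancreas list (4 probes), the muscle list (6), the neural list (8), the blood cell list (9) and the mesenchymal list (5), 0 probes were on with either protein. No member was on in the lists of miR-125, miR-181, miR-130 and miR-301, miR-26, miR-148 and miR-152, the cluster of miR-182, miR-183 and miR-96, miR-196, miR-200, and miR-302 with miR-371 to miR-373 either. These counts cover human probes. The zebrafish probe dre-miR-26b was on with wildtype only, at 595.3 and 108.6. So was dre-miR-454b, at 519.8 and 48.8, and miR-454 belongs to the list of miR-130 and miR-301. The single probe of miR-451, whose maturation uses cleavage by Ago2, was off on both arrays, with a probability of being on of 0.01 with wildtype and 0.19 with mutant Ago2, so these arrays give no difference for it. Of 27 passenger-strand (star) probes, 2 were on with wildtype and 0 with mutant Ago2. Amplitudes of miR-520a* were 1756 and 115.4; that of miR-524* was higher with mutant Ago2, at 260.0, against the direction of its log2 ratio.

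The 3 human probes on on both arrays were those of miR-494, miR-646 and miR-765. With mutant Ago2, 0.64% of the human and 0.5% of the negative probes were on. Unspecific signal at these 3 can therefore not be told apart from bound miRNA. On the mutant array the probability was 0.54 for miR-494 and 0.56 for miR-765, close to the limit of 0.5. A mouse and rat probe of miR-494 was off there, at 102.1 against 1060 with wildtype. The human miR-494 probe sets both the floor of 487.2 behind the bounds and the median on which the mutant array was centred, 1.16. The median of the wildtype array, 2.17, is that of miR-646. The centring therefore does not remove exactly the median difference given below. The amplitude of miR-646 was 1981 with wildtype and 1943 with mutant Ago2, and its log2 ratio differed by -0.25 against a combined SD between replicate spots of 0.41. Amplitudes were 2582 and 487.2 for miR-494 and 1167 and 489.6 for miR-765. Their log2 ratios differed by -1.70 and -1.38, with a combined SD between replicate spots of 0.45 and 0.29 that leaves out the spread between samples. The uncentred shift, the median of the 3 differences, was -1.38, and it turned to 1.55 with loess and 0.35 with the sample channel quantile normalized. After centring, 0 of the 3 were at least 2-fold higher and 0 at least 2-fold lower with mutant Ago2. The SD of their differences was 0.76 and Pearson's r between the arrays was 0.95 (Spearman's rho 0.50, and -0.50 with the sample channel alone) across these 3 miRNAs, which are not replicates. No list had 2 members on on both arrays, so family, cluster and star medians have no value under this rule.

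By the amplitude rule, 48 human probes were again detected with wildtype, 40 of them shared with the probability rule, and 5 with mutant Ago2. Of these, miR-370 (106.0 with wildtype, 492.3 with mutant) and miR-635 (185.9 and 557.2) passed with mutant Ago2 only, so the count of 0 with mutant only became 2 under this rule. That rule also passed 7.96% of the negative probes with wildtype and 4.48% with mutant Ago2, against 10.3% and 1.07% of the human probes, so single dim miRNAs rest on little more than background.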

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

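Tests of the miRNA signal seen on the wildtype array alone were chosen after the result was seen. So were those of opposite errors at dim human probes and of the overall reference difference. The others were written down before.

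Signal stood outside the human miRNA probes. Of the mouse, rat and other animals' probes, 41 were on with wildtype Ago2 and 1 with mutant Ago2. That probe was cel-miR-265, a worm miRNA, with 866.3 with wildtype and 540.8 with mutant Ago2. The probe named for 28S rRNA and a fish miRNA was on on both arrays, at 1342 and 1223.2. The snoRNA E1 probe was on with wildtype only, at 438.6 against 113.0.

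miRNA signal was seen on the wildtype array and not on the mutant array. Weak hybridization of the mutant array as a whole is argued against by its reference channel, whose median ratio of mutant over wildtype was 1.26 over human probes (quartiles 0.945 and 1.70). A lower gain of the sample-channel scan would dim every probe alike, and miR-106a allows at most 12.5% of the wildtype signal to remain. Of the 5 probes on on both arrays, 4 kept over 3 times that share. For cel-miR-265 (62.4%) and miR-765 (41.9%) this follows from their being on, since no probe on there was below 487.2. The argument against a lower gain thus rests on miR-646 with 98.1% and the 28S rRNA probe with 91.1%. A smaller amount of immunoprecipitated Ago2 or of labelled RNA cannot be told apart from weaker miRNA binding by the mutant, since each group is 1 array and the 3 human miRNAs on on both are too few to test for a common factor. The mutation itself remains an open, untested explanation.

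Some dim human probes had an uncentred log2 ratio at least 2-fold higher on the mutant array, 96 of the 419 off on both, while 39.9% of the 419 were at least 2-fold lower, against 32.7% of the negative probes off on both. For binding to mutant Ago2, the share was 22.9% in human and 32.1% in negative probes, a difference of -9.23 percentage points. Human probes thus showed no excess, but this cannot decide on binding of single miRNAs. The reference was on for 121 (wildtype array) and 151 (mutant array) of 467 human probes, against 17 and 21 of 201 negative probes. Weak signal with wildtype would also lower the human share. Opposite errors of the channels at dim spots are a candidate explanation, since the channels' amplitudes were anticorrelated over negative probes off in both (Spearman's rho -0.364 with wildtype, -0.41 with mutant Ago2).

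The reference channel was dimmer on the wildtype array at the 48 human probes on there, with a median log2 difference of -1.10 (wildtype minus mutant) against -0.28 at the 419 others. An overall difference of the reference is argued against by a percentile of 0.0 among matched sets of off probes. Opposite errors at spots with a dim reference are argued against by the same percentile of 0.0 over the 18 probes with the reference on on both arrays. Competition of labelled RNA with the reference for the same probe stays open. The test written for it, Spearman's rho of 0.11 with the sample amplitude, ranks levels of different probes, which are not comparable, and so decides nothing.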

How the results depend on the processing

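The alternatives without centring, with loess for the shift, with amplitude limits, with the ratio of mean amplitudes and for the lower bounds were chosen after the data were seen. No paired analysis was possible because each group had 1 sample, which also rules out leaving out a replicate. Normexp, a comparison without background correction and the median of replicate spots were not run, since the files hold neither a background nor single spots. Stricter detection, the reference filter and the 6 SD limit left 1 probe on on both arrays and gave no value for the results on such probes. Under the alternatives 47 values were labelled the same as the main one, 33 moved and 5 reversed. The 47 include a lower-bound count of 16 against 24 and an SD of 1.09 against 0.76. Many could not change, since centring leaves the SD and the correlations as they are and some filters kept the same probes. The series matrix repeats the sample channel alone. These counts therefore do not measure robustness. The causes of moves and reversals were not tested, except that fewer or more probes pass under other filters.

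Detected human probes went from 48 with wildtype and 3 with mutant Ago2 to 25 and 1 above a probability of 0.9, to 18 and 1 with the reference channel also on, and to 24 and 1 above the median plus 6 SD. Above the median plus 3 SD the mutant array had 5. miRNAs on with wildtype only went from 45 to 24, 17 and 23 under the first 3 of these. The lower bound of at least 2-fold went from 24 miRNAs to 37 without centring, to 0 with the sample channel alone centred and to 15 with it not centred; loess gave 16, and 9 had the reference channel also on.

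The results on 3 probes depend on the scaling. The uncentred shift reversed from -1.38 to 1.55 with loess and to 0.35 with quantile normalization of the sample channel. Spearman's rho reversed from 0.50 to -0.50 with the sample channel alone, with its quantile normalization and with the series matrix. The count at least 2-fold higher with mutant Ago2 went from 0 to 2 with loess, and to 1 with the sample channel alone, with its quantile normalization and with the series matrix. The count at least 2-fold lower went from 0 to 1 with quantile normalization and to 2 without centring. The SD of the differences went from 0.76 to 1.19 with the sample channel alone and with the series matrix. Pearson's r went from 0.95 to 0.19 with both of these and to 0.17 with quantile normalization. Without a detection filter, over 467 probes, the shift was -0.78, 139 were at least 2-fold higher and 156 lower, the SD was 2.45, r was 0.19 and rho 0.245; 26 lists and 27 star probes then had a median, against 0 and 0. Signal over background in the sample channel, 2.49 on the mutant array, limits what its dim probes can show.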

Other observations

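Probes for other animals' miRNAs were also on mainly with wildtype Ago2. Of the 119 probes of other animals with a mammalian counterpart by name, 19 were on with wildtype and 0 with mutant Ago2, and of the 246 mouse or rat probes 14 and 0. The zebrafish probe dre-miR-20b had an amplitude of 2980 with wildtype and 101.5 with mutant Ago2, and the mouse probe mmu-miR-106a had 2108 and 221.4. The mouse probe mmu-miR-709, with no human probe of that name among those on, had 3951 and 432.6. Its lower bound in the sample channel, 8.11-fold, was above the 8.01-fold of miR-106a. Which RNA bound this probe was not tested, so signal on with wildtype only need not be the miRNA a probe is named for. These probes were named after their values were seen.

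Without a detection filter, and centred on all human probes, the median log2 difference (mutant minus wildtype) was -5.34 for miR-103 and miR-107, at percentile 0.03 among random matched lists. It was -4.11 for the cluster from miR-17 to miR-92 (percentile 0.11), -3.94 for the miR-17 seed family (0.12) and -3.13 for the miR-15 and miR-16 family (0.84). Other lists with members on with wildtype were less extreme. The median was -3.40 for miR-221 and miR-222 (4.96), -2.68 for the miR-30 family (9.43) and -2.81 for the miR-106b, miR-93 and miR-25 cluster (14.6). For the muscle list it was 0.89 (80.3), for the neural list 0.43 (62.2) and for the star probes -0.48 (40.02). These percentiles describe 1 pair of arrays, and most members were off with mutant Ago2, so the medians are not measured folds.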
